A study of Arabidopsis thaliana with 2 samples.

How the data were processed

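Methylation of genomic DNA was measured by bisulfite sequencing in 2 libraries of Arabidopsis thaliana ecotype Ws-0, 1 from hand-dissected seed coats and 1 from hand-dissected embryos of mature green seeds, 13 days after pollination. Bisulfite converts unmethylated cytosine to uracil, which is read as thymine, while methylated cytosine is still read as cytosine. Per the labels' protocols, DNA was isolated with a column kit, ligated to adapters, treated with bisulfite repeatedly, amplified by PCR and size selected, and unmethylated lambda DNA was added as a conversion control. More input DNA entered the embryo library than the seed coat library, per the labels. Reads of the lambda control were not analysed here, so no conversion rate from it was used.

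The deposited files give, for each cytosine, the counts of methylated and of unmethylated calls, its strand and its context: CG, CHG or CHH, where H is A, C or T. The deposited fraction of methylated calls in the last column equalled the ratio of the counts to within 5.27e-07. The authors' values are therefore raw counts with no normalization, and the counts were tested here, not the fraction. The genome build named is TAIR10, per the submitters' processing notes, but the positions in the files put this in doubt, as described with the coordinates. The aligner, the treatment of PCR duplicates and the filters on reads are not given in the sources used here. The reads carry no molecular identifiers that the labels mention, so PCR copies can count more than once and every binomial interval covers counting error only.

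A filter is visible in the values of both deposited files. No cytosine is listed with fewer than 2 calls, and none with exactly 1 methylated call, although 30883450 seed coat and 31262603 embryo cytosines are listed with 0 methylated calls and 596125 and 565186 with 2. Such a filter lowers low methylation levels by an amount that depends on depth. Levels were computed on the counts as deposited, and again with absent cytosines filled in. A cytosine absent from 1 library and listed with at least 4 calls in the other was set to 1 methylated call out of the mean depth of the listed cytosines on the same strand in the same 200 bp stretch, where at least 3 were listed. This filled in 2208324 cytosines in the seed coat library and 1651121 in the embryo library. In simulated CHH counts at a level of 0.2% for the seed coat library on chromosome 4, the filter left 0.0247% and filling in gave 0.192%.

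Coordinates are those of the deposited files and were not assigned to genes. The gene table used here is of assembly TAIR10.1. On each of the 5 chromosomes the last listed cytosine lay 303 to 445 kb short of the end of the last gene in that table, and 119 to 163 genes per chromosome began beyond it. In 625 tRNA genes of that table, the conserved cytosines 12 and 17 bases before the gene end were found at 29.1% and 29.1% of the genes, against 25.3 to 32.6% at the other offsets up to 40. The files' positions are thus not positions of TAIR10.1, whose nuclear coordinates are those of TAIR10. Which build they follow is not established, so every printed coordinate holds within the deposited files only. The planned comparisons by annotated feature, gene body, upstream region and fixed gene list were not run, and no gene, exon or UTR is named. In their place, chosen after the data were examined, 500 bp windows were put into classes by the mean of both libraries' levels: CHG-methylated (CHG at least 20%), CG-only (CG at least 20% and CHG under 5%) and low (CG and CHG both under 5%). Bins of 100 kb with a mean CHG level of at least 20% were called CHG-rich, and those under 5% CHG-poor.

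The genome-wide comparison and the tests of windows and of single cytosines were fixed before the data were examined; the comparisons by window class, CHG level, location, overlap of calls, depth of called windows and distribution of CG levels were chosen afterwards. The level of a group of cytosines is the sum of methylated calls over the sum of all calls at cytosines with at least 4 calls in both libraries. Differences are embryo minus seed coat in percentage points, with a 95% interval from a paired bootstrap over 100 kb bins (1000 draws), and were called different when the interval left out 0. Windows of 500 bp with at least 4 (CG, CHG) or 8 (CHH) such cytosines were compared by a two-sided Fisher's exact test on summed counts with Benjamini-Hochberg adjustment within the context. A window was called at an adjusted p under 0.01 and a difference of at least 30 (CG), 20 (CHG) or 10 (CHH) points. Single cytosines with at least 10 calls in both libraries were called at an adjusted p under 0.05. With 1 library per group there is no replicate check, and each test compares these 2 libraries, not the tissues. The rule for named genes could not be applied. The windows named are, per context, the 3 called windows with the largest positive and the 3 with the largest negative difference. This rule replaced that for genes and was not part of the original plan.

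Alternatives were other minimum depths, the unweighted mean of cytosines, all covered cytosines of each library, removal of cytosines above the 99th percentile of depth, thinning of the deeper library to the total of the shallower, single strands, omission of each chromosome, other window sizes and other minimum differences. The fill-in, the subtraction of a background, the limits of the window classes and the removal of the deepest cytosines from the comparisons by CHG level, location and length of methylated stretches were additions chosen after seeing the data. The window test was checked on simulated counts on chromosome 4 with 200 changed windows: 199 were recovered at a CG difference of 45 points, 185 at a CHG difference of 30 points and 197 at a CHH difference of 15 points. Of 100 simulated genomes without a difference, the bootstrap interval held 0 in 93. Their bins held independent binomial counts without very deep stretches or PCR copies, so the intervals of the deposited data were not checked in their own setting. Computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Numba 0.67.0, and figures Matplotlib 3.10.9.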

Results

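Cytosine methylation was measured by bisulfite sequencing in the 2 parts of the mature green Arabidopsis seed that were separated by hand, the seed coat (1 library) and the embryo (1 library), at 13 days after pollination. The seed coat is maternal tissue that encloses the embryo. The seed coat file held 1247560179 calls at 34427473 cytosines (median 36 calls per cytosine) and the embryo file 870092976 calls at 34742774 cytosines (median 24). Both files listed 32387990 of these cytosines. Because each tissue was represented by 1 library, differences had no replicate check, and intervals describe the spread over the genome or counting error within these libraries.

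The comparison asked how methylation differs between the embryo and the seed coat. Methylation was higher in the embryo library in all 3 sequence contexts, and by the largest factor in CHH. CHH methylation was 1.12% in the seed coat library and 1.86% in the embryo library, a difference of 0.732 points (95% bootstrap interval 0.583 to 0.926) and a ratio of 1.65 (1.59 to 1.71). CG methylation was 23.2% against 24.9%, a difference of 1.66 points (1.41 to 1.96), and CHG methylation 7.23% against 7.84%, a difference of 0.617 points (0.433 to 0.861). Wilson 95% intervals for counting error were 1.12 to 1.12% for CHH in the seed coat library and 1.85 to 1.86% in the embryo library, at a mean depth of 36.7 and 24.8 calls per cytosine. With absent cytosines filled in, the CHH levels were 1.24% and 1.98% (ratio 1.60, 1.54 to 1.66), the CG levels 21.6% and 23.0%, and the CHG levels 6.71% and 7.13%.

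The CHG difference was regional. The embryo library was higher in CG in 90.6% and in CHH in 83.6% of the 1175 bins of 100 kb, but in CHG in only 30.6% of them, so the pooled CHG difference and the sign of the typical bin went opposite ways. In the coordinates of the deposited files, whose genome build is in doubt, the 214 CHG-rich bins lay between 12600000 and 16799999 on chromosome 1, 1200000 and 10299999 on chromosome 2, 10800000 and 16399999 on chromosome 3, 1600000 and 5899999 on chromosome 4, and 8300000 and 17299999 on chromosome 5. In them CG methylation rose from 61.7% in the seed coat library to 70.6% in the embryo library, CHG from 39.9% to 47.1% and CHH from 6.30% to 11.1%. All 214 were higher in the embryo library in CHG and in CHH, and 213 in CG. In the 831 CHG-poor bins CG differed by 0.525 points (14.5% against 15.1%) and CHH by 0.0502 points (0.159% against 0.209%). CHG went the other way there, 0.937% in the seed coat library against 0.760% in the embryo library, and only 56 of these bins were higher in the embryo library. The size of the pooled differences depended on how cytosines were weighted. Without weighting by depth the CG and CHG differences were 2.71 and 1.24 points, over all covered cytosines of each library 0.966 and 0.178 points, and without cytosines above the 99th percentile of depth the CHG and CHH differences were 0.354 and 0.466 points.

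**Figure D1:**
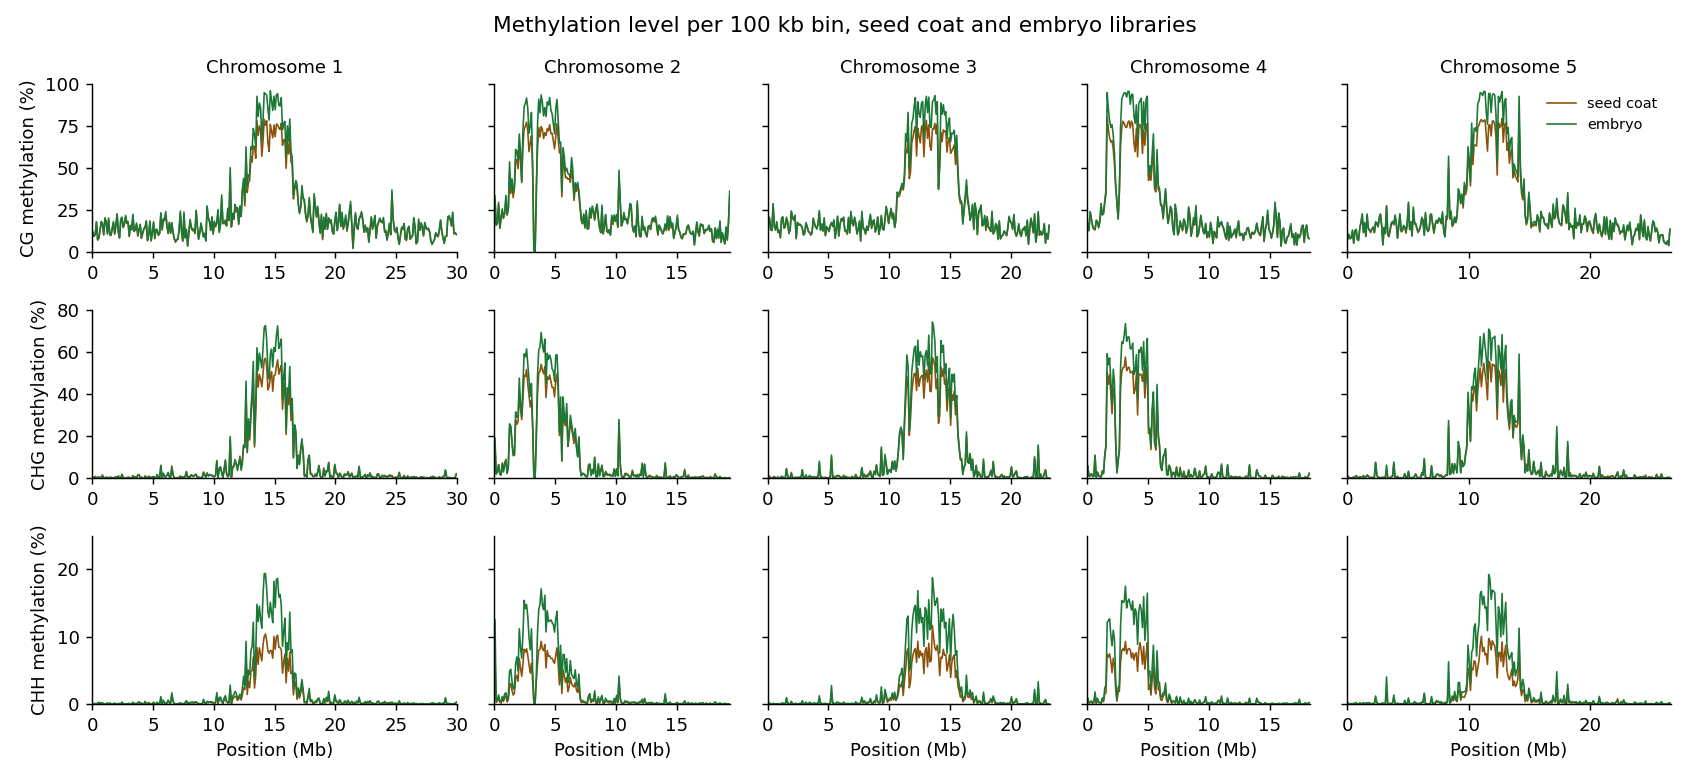
Methylation level in percent (y axis) per 100 kb bin along the 5 chromosomes (x axis, Mb, coordinates of the deposited files) for CG, CHG and CHH, with the seed coat library in brown and the embryo library in green. The libraries part in the methylated block of each chromosome, where CHH averaged 6.30% in the seed coat and 11.1% in the embryo library. They nearly coincide over most of the arms, but CHH also parts at the start of chromosome 2.

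The difference was largest in windows with CHG methylation, a mark found mostly at transposons and repeats in plants. In the 30821 CHG-methylated windows CG methylation was 71.6% in the seed coat library and 81.7% in the embryo library (difference 10.1 points, 6.49 to 13.3), CHG methylation 49.2% and 57.7% (8.52 points, 6.89 to 9.90), and CHH methylation 8.27% and 14.5% (6.20 points, 5.95 to 6.53). The embryo library was higher in 93.3% of these windows in CG, 84.4% in CHG and 96.6% in CHH. The median window differed by 14.1 points in CG. With absent cytosines filled in, CHH was 7.0% and 12.5%, a ratio of 1.79 (1.78 to 1.81).

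CHG-methylated windows outside the CHG-rich bins showed a slightly lower CHH ratio and a smaller CG and CHG excess. With absent cytosines filled in, the CHG excess was not found in short stretches there. In the 8620 such windows the ratio of embryo to seed coat was 1.68 (1.65 to 1.72) for CHH, 1.08 (1.04 to 1.11) for CG and 1.08 (1.06 to 1.10) for CHG. In the 22201 windows within the CHG-rich bins it was 1.76 (1.75 to 1.78) for CHH, 1.16 (1.10 to 1.20) for CG and 1.19 (1.16 to 1.22) for CHG. The CG intervals of both locations overlapped, but cytosines above the 99th percentile of depth held 36.1% of the embryo CG calls in the windows within the CHG-rich bins and 24.4% outside them. Without these, and with absent cytosines filled in, the CG ratio was 1.18 (1.18 to 1.19) within and 1.09 (1.09 to 1.10) outside. By the same count, outside the CHG-rich bins, CHG showed no detectable difference in the 2124 windows without a CHG-methylated neighbour (-0.312 points, -1.36 to 0.535) and was lower in the embryo library in the 3069 windows in runs of 2 to 3 (-1.35 points, -1.99 to -0.699). CG was higher in the embryo library in both, by 3.40 (2.71 to 4.10) and 4.31 points (3.74 to 4.88), and so was CHH, by 5.35 (5.05 to 5.64) and 4.26 points (4.01 to 4.50). With the deepest cytosines kept, the CG differences were 0.944 (-2.22 to 4.23) and 1.31 points (-0.971 to 5.10). By run length, windows outside the CHG-rich bins were computed only with absent cytosines filled in. The fill-in lowered the CHG difference: in runs of 2 to 3 over all bins it was 3.39 points as deposited and 2.53 filled in. The sign of the CHG difference as deposited outside the CHG-rich bins is therefore not known for these runs.

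CG-only windows, the pattern usual for methylated gene bodies, showed a smaller CG excess and a lower CHG level in the embryo library. In the 39314 CG-only windows CG methylation was 54.0% in the seed coat library and 57.6% in the embryo library (3.53 points, 3.45 to 3.62), and 79.7% of the windows were higher in the embryo library. CHG methylation in these windows was lower in the embryo library, 0.270% against 0.149% as deposited and 0.529% against 0.326% filled in. CHH methylation was 0.0677% and 0.0634% as deposited, and the sign of this difference depended on the processing. In the 120897 low windows all contexts were at or below 0.272% in both libraries with absent cytosines filled in, and the embryo library was the lower one: CHH was 0.161% in the seed coat library and 0.129% in the embryo library, and CHG 0.207% and 0.125%. The CHG ratio of embryo to seed coat was 0.601 (0.591 to 0.611) there and 0.617 (0.608 to 0.627) in CG-only windows, so the lower CHG level was not specific to CG-only windows.

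**Figure D2:**
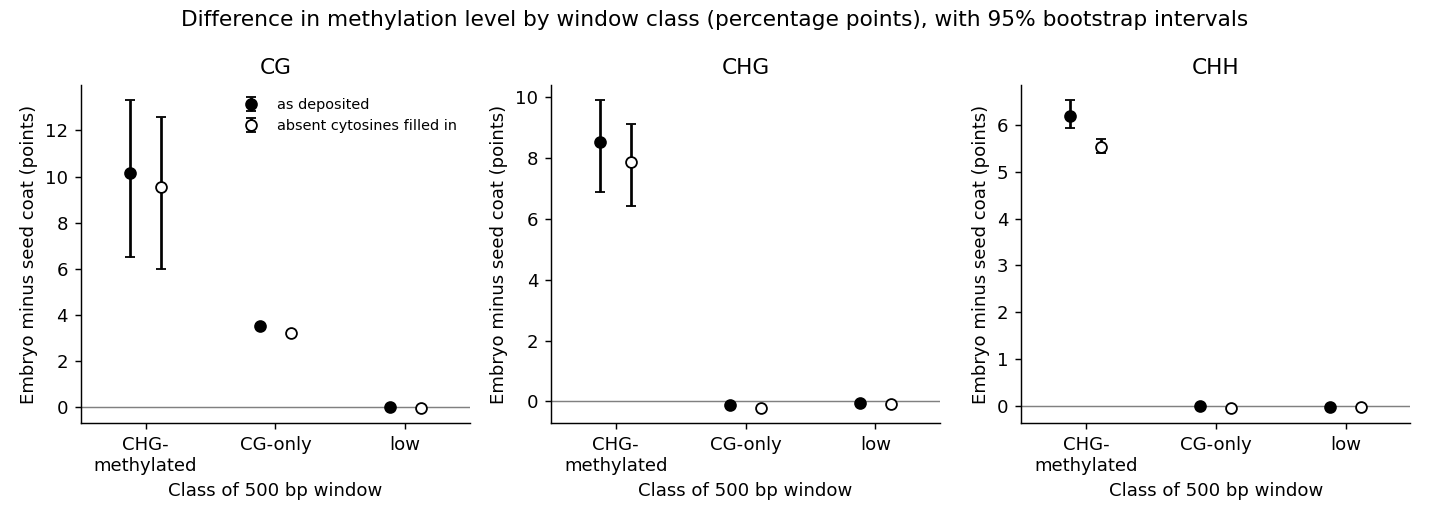
Difference in methylation level, embryo minus seed coat, in percentage points (y axis) for CHG-methylated, CG-only and low 500 bp windows (x axis), as deposited (filled circles) and with absent cytosines filled in (open circles), with 95% bootstrap intervals over 100 kb bins; intervals narrower than the symbol are hidden by it. CHG-methylated windows differed by 10.1 points in CG, 8.52 in CHG and 6.20 in CHH as deposited, and low windows by less than the height of the symbols.

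Sorting windows by their CHG level separated the contexts. With absent cytosines filled in, the ratio of embryo to seed coat CHH was 0.799 (0.792 to 0.806) in windows below 1% CHG, 1.94 (1.81 to 2.01) at 10 to 20%, peaked at 2.02 (1.96 to 2.07) at 20 to 30%, and was 1.75 (1.73 to 1.77) at 60% and above. The CG ratio was 1.04 (1.04 to 1.05) below 1% CHG and 1.07 (1.06 to 1.07) at 1 to 5%, and reached 1.18 (1.18 to 1.19) at 60% and above, where CG levels were 78.4% in the seed coat library and 92.6% in the embryo library. Between these, the CG interval held 1 at 5 to 10% CHG (0.979, 0.936 to 1.05), at 10 to 20% CHG (0.985, 0.946 to 1.07) and at 20 to 30% CHG (1.04, 0.995 to 1.14), where cytosines above the 99th percentile of depth held 32.9%, 44.0% and 66.7% of the embryo CG calls. Without these cytosines the CG ratio was above 1 in each, at 1.04 (1.03 to 1.06), 1.03 (1.01 to 1.05) and 1.11 (1.09 to 1.12), and the CHH ratio was still 2.002 (1.93 to 2.08) at 20 to 30%.

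**Figure D3:**
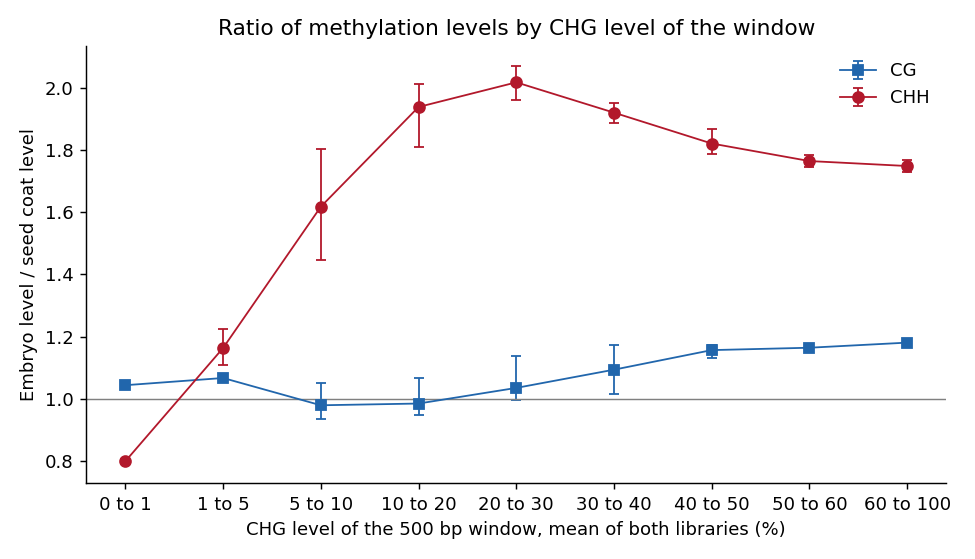
Ratio of embryo to seed coat methylation level (y axis) in CG (blue squares) and CHH (red circles) for 500 bp windows grouped by their CHG level, the mean of both libraries in percent (x axis), with absent cytosines filled in and 95% bootstrap intervals. CHH rises to 2.02 at 20 to 30% CHG and falls to 1.75 at 60% and above, while CG reaches 1.18 there.

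Levels of single CG sites also differed in their distribution. Of 3925832 CG cytosines with at least 10 calls in both libraries, 22.1% were at 80% or more in the embryo library and 15.7% in the seed coat library. Levels above 20% and below 80% were found at 4.57% of them in the embryo library and at 10.9% in the seed coat library. The share without a methylated call was 72.5% and 72.1%.

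At the level of 500 bp windows and with minimum differences of 30 points in CG, 20 in CHG and 10 in CHH, most calls were in CHH and nearly all of these were higher in the embryo library. Of 220256 windows tested in CHH, 7566 were higher and 118 lower in the embryo library. In CHG 1919 were higher and 475 lower of 211030, and in CG 572 were higher and 96 lower of 211747. With absent cytosines filled in, 567 CG windows were higher and 207 lower, a share higher of 73.3% in place of 85.6% that came from the added lower calls. The fill-in itself may make such calls, because it sets absent cytosines to 1 methylated call. CG cytosines with 10 to 20 methylated calls in the seed coat library were absent from the embryo library at 1.24%, against 0.0576% the other way. CHG-methylated windows held 79.1% of the CHH windows that were higher, against 13.9% of all windows tested (odds ratio 28.7). CG-only and low windows, 17.8% and 54.9% of those tested, held 5 and 0 of these calls. Their CHH level was at or below 0.216% in both libraries with absent cytosines filled in. The odds ratio thus largely reflects which windows carry CHH methylation at all. Higher and lower CHG windows had different locations: 72.6% of the former and 16.4% of the latter lay in CHG-rich bins. These bins held 14.8% of the windows tested, but CG-only and low windows held 0 of the CHG calls. CHG-methylated windows, which held 88.8% of the higher and 68.4% of the lower calls, lay mostly in CHG-rich bins (22201, against 8620 in other bins). Against that split, all higher calls were divided much alike (1394 in CHG-rich and 525 in other bins), while all lower calls were not (78 and 397). These counts include calls outside CHG-methylated windows, and calls within that class alone were not divided by location. Among the 30706 CHG-methylated windows tested in CHG and CHH, both contexts were higher in 700, against 330.5 for independent calls, and both were lower in 48, against 0.614. In CG and CHG 66 such windows were higher in both, against 17.1, while in CG and CHH 59 were, against 59.2.

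These calls rest on Fisher's exact test between 2 libraries and on set minimum differences. Without a minimum difference 36048 windows were called in CG, 16216 in CHG and 34316 in CHH, and 93.5%, 86.0% and 93.6% of them were higher in the embryo library. Minimum differences of 40, 30 and 20 points left 96, 342 and 1190 windows, and the share higher in the embryo library in CHG then fell from 80.2% to 57.3%. With windows of 200 bp 1975, 5788 and 18990 were called, and with windows of 1000 bp 164, 836 and 3087. Depth differed with the CHH calls: in the CHH windows that were higher in the embryo library, that library had 0.641 times the calls per cytosine of low windows within 5 kb, and the seed coat library 0.914 times. In the CHH windows that were lower the embryo library had 0.914 times, and the seed coat library 0.617 times. These values cover only called windows with at least 3 low windows within 5 kb, 3119 of 7566 higher and 98 of 118 lower.

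Windows were named in both directions by rule, although large changes were mostly higher in the embryo library in CG and CHH. At minimum differences of 40 points in CG and 20 in CHH, 83 CG windows were higher and 13 lower, and 1188 CHH windows were higher and 2 lower. In CHG, at 30 points, 196 were higher and 146 lower. On chromosome 1, 6072000 to 6072499, CG methylation was 21.8% in the seed coat library (Wilson 95% interval 18.2 to 25.8, 450 calls) and 79.9% in the embryo library (74.6 to 84.4, 254 calls), with an adjusted p of 6.01e-50 by Fisher's exact test. CHG there was 13.1% against 71.6% and CHH 7.24% against 26.2%. On chromosome 3, 11192000 to 11192499, CHG methylation was 23.5% (19.2 to 28.4, 324 calls) and 87.7% (80.4 to 92.5, 114 calls), CHH 9.10% and 53.5%, and CG 84.6% and 91.5%. On chromosome 2, 10476500 to 10476999, CHH methylation was 29.6% (24.5 to 35.3, 270 calls) and 90.1% (83.5 to 94.2, 121 calls). In the other direction, CG methylation on chromosome 5, 20886500 to 20886999, was 75.8% over 43 cytosines in the seed coat library (73.9 to 77.5, 2132 calls) and 26.2% in the embryo library (24.0 to 28.5, 1433 calls).

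Several of the windows that were lower in the embryo library had no listed methylated call there in any context. On chromosome 5, 6384000 to 6384499, CHH methylation was 19.5% in the seed coat library (17.3 to 21.9, 1136 calls) and 0 of 1442 calls in the embryo library, with CHG at 29.7% against 0% and CG at 24.7% against 0%. CHG methylation on chromosome 2, 10714000 to 10714499, was 57.4% (47.7 to 66.6, 101 calls) against 0 of 71 calls. On chromosome 5, 22297500 to 22297999, it was 50.2% (43.6 to 56.8, 217 calls) against 0 of 196 calls, with CG at 31.0% against 0% and CHH at 14.4% against 0%. Because cytosines with 1 methylated call are missing from the files, these zeros set no upper limit. The other 11 of the 18 named windows had differences between -50.8 and 70.9 points in the context that named them. Filling in absent cytosines lowered 3 of these by over 1.5 times, from 65.2 to 41.3 and from 60.03 to 37.9 points in CHG and from 55.6 to 35.9 points in CHH.

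**Figure D4:**
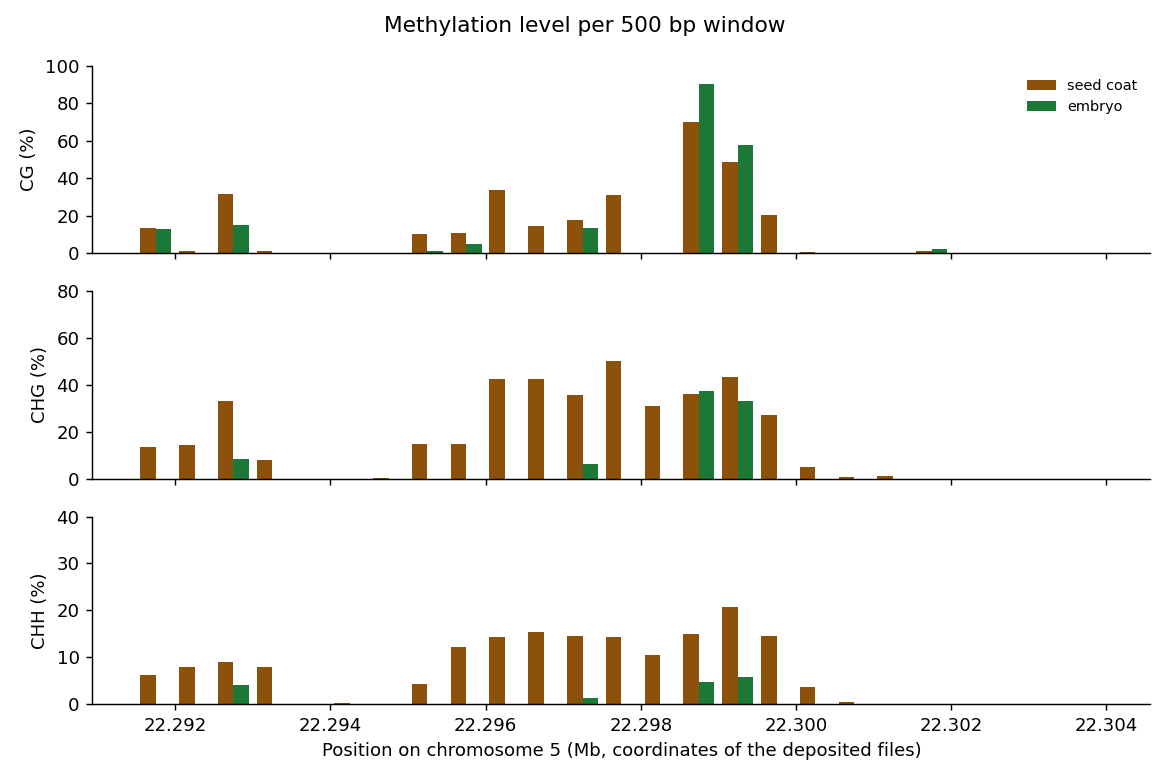
Methylation level in percent (y axes) per 500 bp window on chromosome 5 from 22291500 to 22303999 (x axis, Mb, coordinates of the deposited files) for CG, CHG and CHH, with bars for the seed coat library in brown and the embryo library in green; the region, around a window named above, was picked after its values were seen. CHG reaches 50.2% in the seed coat library at 22297500, where the embryo library has 0%, while both libraries are methylated in CG at 22298500 (70.0% and 90.2%).

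Single cytosines gave the same directions. With at least 10 calls in both libraries, 26381 CG cytosines were higher and 3074 lower in the embryo library, 4192 CHG cytosines were higher and 838 lower, and 13886 CHH cytosines were higher and 248 lower. CHG-methylated windows held 67.9% of the CG, 84.2% of the CHG and 79.1% of the CHH cytosines called, against 12.7%, 11.5% and 8.65% of those tested. For CHG part of this is built in, because the windows were classed by the CHG level of the same libraries. For CHH it partly reflects which windows carry CHH methylation. Many of these calls were at very deep cytosines: without those above the 99th percentile of depth, 14051 CG, 1555 CHG and 4793 CHH cytosines were called. In CHG 1038 of these were higher and 517 lower, so the share higher fell from 83.3% to 66.8%. With the seed coat library thinned to the depth of the embryo library, 3133 CHG and 9023 CHH cytosines were called.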

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

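The tests in this part were chosen after the results were seen, except the tests of removal at unequal depth and of over-conversion, which were set before their values were seen.

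Cytosines listed in only 1 library entered, as deposited, only the alternative over all covered cytosines of each library, and they carried methylated calls. The 2039483 cytosines listed in the seed coat library only had a median of 27 calls and levels of 4.24% in CG, 3.52% in CHG and 1.51% in CHH. The 2354784 cytosines listed in the embryo library only had a median of 25 calls and levels of 0.746% in CG, 0.566% in CHG and 1.89% in CHH. Their depth in the library that lists them is far above the minimum of 2 calls. Removal of cytosines with 1 methylated call before deposit predicts that absence is more frequent at cytosines with few methylated calls in the other library than at those with none. At 20 to 40 calls in the other library, cytosines with 2 methylated calls there were absent at least 2.04 times (1.97 to 2.11) as often as those with 0, in each context and library. The higher CG and CHG levels of the cytosines listed in the seed coat library only stay open. Cytosines with 10 to 20 methylated calls in the seed coat library were absent from the embryo library at 1.24% in CG and 2.02% in CHG, and those with as many in the embryo library were absent from the seed coat library at 0.0576% and 0.0641%. No biological explanation was tested for this pattern.

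The CHH excess of the embryo library in CHG-methylated windows was tested against technical explanations. Incomplete conversion of the embryo library would raise CHH in low windows too, where the embryo library was lower, with a difference of -0.0319 points (-0.0335 to -0.0304) with absent cytosines filled in. In a very deep stretch of chromosome 2, described below, the embryo library was higher by the same count, at 0.320% against 0.260%. Both levels there were far below the CHH excess of 5.54 points in CHG-methylated windows. Removal of cytosines with 1 methylated call at unequal depth was tested by filling in, thinning the seed coat library and repeating the removal. The ratio of embryo to seed coat CHH was then 1.75 (1.74 to 1.76), which argues against it as the cause. A tissue difference stays open, untested, and cannot be separated from any difference in library preparation, because each tissue has 1 library.

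The lower CG level of the seed coat library in CHG-methylated windows was tested in the same way. Over-conversion would take the same share of methylated calls everywhere. At CG cytosines of 95% or more in the embryo library, the seed coat level was 87.1% in CG-only and 81.9% in CHG-methylated windows, 5.22 points apart (4.87 to 5.57), so a loss alike everywhere is not the whole cause, although part of it may be. Admixed DNA without methylation would likewise give 1 ratio in both classes. The ratio of embryo to seed coat in CHG-methylated windows was 1.07 times that in CG-only windows (1.03 to 1.11). Such admixture is thus not the whole cause, although part of it may be. A few strongly changed windows are excluded by a median window difference of 14.1 points. Open are a tissue difference, a second cell population in the seed coat sample with less methylation in such windows, and library preparation; the gene list fixed as markers of another seed tissue could not be used without gene coordinates.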

How the results depend on the processing

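The fill-in, the background subtraction and all alternatives for window classes were chosen after seeing the data. Of 126 alternative values of the genome-wide, class and call results, 107 kept their direction and their side of the threshold or stayed within 1.5 times the count; all 82 values of the named windows kept their direction and their call. Filling in moved 3 named windows by over 1.5 times (CHG from 65.2 to 41.3 and from 60.03 to 37.9 points, CHH from 55.6 to 35.9), and gave 567 higher and 207 lower CG windows in place of 572 and 96. The genome-wide differences ranged from 0.966 to 2.71 points in CG, 0.178 to 1.24 in CHG and 0.466 to 0.836 in CHH, and in CHG-methylated windows from 9.54 to 13.2, 7.86 to 9.75 and 5.54 to 6.60. CHH in CG-only windows reversed with the mean of single cytosines (0.00946 points) and after filling in, thinning and repeated removal (0.00337 points); the cause was not tested. Removing cytosines above the 99th percentile of depth, also chosen after seeing the data, kept 53 of 60 differences by CHG level, location and length of methylated stretches. CG at 5 to 10% and 10 to 20% CHG turned from -0.550 and -0.581 points, with intervals that held 0, to 1.35 and 1.09 points, and 5 CG differences moved past the threshold, higher in the embryo library. Called windows numbered 1975, 5788 and 18990 (CG, CHG, CHH) at 200 bp and 164, 836 and 3087 at 1000 bp, where fewer windows are tested. By construction, stricter differences gave 96, 342 and 1190, and no minimum difference 36048, 16216 and 34316. Called cytosines fell to 14051, 1555 and 4793 without those above the 99th percentile of depth, and to 3133 (CHG) and 9023 (CHH) with the seed coat library thinned, both with fewer calls to test. A minimum of 1 read equals the files' own minimum of 2. Not run for lack of gene coordinates: every alternative for feature classes, gene bodies, upstream regions and gene lists, and the coding-sequence background. Some named windows had too few cytosines at 10 reads and gave no value. No paired analysis was possible because each group has 1 library. Depth limits low levels most: below 1% they shift with the missing cytosines of 1 methylated call.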

Other observations

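All tests in this part were chosen after seeing the data, except the test of island length, which was set before its value was seen.

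A set of windows was methylated in the seed coat library and under 1% in the embryo library in the counts as deposited. Because cytosines with 1 methylated call are missing, absence of methylation in the embryo library is not shown. Of 205788 windows with a level in every context, 93 were under 1% in CG, CHG and CHH in the embryo library and at 20% CHG or more in the seed coat library, and 0 were the other way round. The 93 windows fell into 59 regions more than 5 kb apart, so they are not independent of each other. With the CHG limit at 10% the counts were 187 and 0, and with the embryo limit at 5% they were 109 and 1. In the seed coat library their median levels were 19.6% in CG, 28.9% in CHG and 9.76% in CHH. CHG exceeded CG in 88 of the 93, an order found in 3.40% of the CHG-methylated windows. These shares are not matched: the 93 were chosen by seed coat CHG, with no lower limit on seed coat CG. The CHG-methylated windows were chosen by the mean of both libraries and were at 71.6% CG and 49.2% CHG in the seed coat library. The windows lay on all 5 chromosomes (22, 15, 10, 19 and 27 on chromosomes 1 to 5) and 5 of them in CHG-rich bins. The hypothesis that reads from a methylated copy elsewhere were added to the seed coat counts predicts extra depth there. In 89 of the 93, the seed coat library had 0.622 times (0.565 to 0.661, resampling windows) the calls per cytosine of low windows within 5 kb. The embryo library had 0.939 times (0.902 to 1.01). No extra depth was seen. The seed coat library had a like 0.617 times in CHH windows called lower in the embryo library, but the 2 sets share windows, such as 6384000 to 6384499 on chromosome 5. In CHG-methylated windows outside the CHG-rich bins, at 8.34% CHH in the seed coat library, that library had 0.941 times. Its depth thus did not fall wherever it carried CHH methylation. The cause of the low depth in the 93 windows was not tested. Whatever lowered it could hide added reads, so this test cannot decide.

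In CHG-methylated windows the CHG excess of the embryo library depended on the base after the cytosine. CAG and CTG sites were at 54.5% in the seed coat and 65.5% in the embryo library (ratio 1.20, 1.18 to 1.22), and CCG sites at 32.1% and 34.0% (ratio 1.06, 1.02 to 1.10).

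Where it could be compared, depth went with CHH methylation in the CHH windows called in either direction, and less clearly or not at all with CG methylation. Only windows with at least 3 low windows within 5 kb entered. These were 3119 of 7566 CHH windows higher in the embryo library and 98 of 118 lower. In CHG they were 608 of 1919 and 399 of 475, and in CG 202 of 572 and 75 of 96. In CHH windows that were higher in the embryo library, the embryo library had 0.641 times the calls per cytosine of low windows within 5 kb and the seed coat library 0.914 times, and the median ratio of embryo to seed coat was 0.719 (0.712 to 0.725). In CHH windows that were lower in the embryo library these were 0.914 and 0.617 times, and the ratio was 1.54 (1.49 to 1.60). The ratio was 0.769 (0.749 to 0.787) in CHG windows that were higher and 1.06 (1.01 to 1.13) in those that were lower, and 0.885 (0.843 to 0.901) and 0.971 (0.924 to 1.03) in CG windows. CG-only windows had 1.11 times the calls of low windows within 5 kb in both libraries (ratio 1.002, 1.001 to 1.004). No loss of fragments methylated in CG alone was thus seen. It is not excluded, because the 2 kinds of window were not matched in sequence. A candidate explanation is that fragments with CHH methylation are under-represented in the counts of either library. It was found and tested on the same data, and which step might cause it was not tested.

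The hypothesis that long methylated stretches carry the larger CHH gain was tested on the ratio of embryo to seed coat, which was lower in long stretches, while the gain in points was alike. With absent cytosines filled in, the ratio of embryo to seed coat CHH was 2.09 (2.04 to 2.14) in single CHG-methylated windows and 1.77 (1.75 to 1.80) in runs of 10 or more, 0.850 times that of single windows (0.818 to 0.880). CHH rose from 5.29% to 11.04% in single windows, by 5.74 points (5.54 to 5.96), and from 7.43% to 13.2% in runs of 10 or more, also by 5.74 points (5.52 to 5.99). As deposited the gains were 6.24 (6.003 to 6.51) and 6.57 points (6.16 to 7.05). The other contexts went the opposite way to the CHH ratio: the ratio was 1.05 (0.988 to 1.12) in single windows (1.08, 1.07 to 1.10, without cytosines above the 99th percentile of depth) and 1.19 (1.18 to 1.19) in runs of 10 or more in CG, and 1.07 (1.05 to 1.10) and 1.21 (1.20 to 1.22) in CHG. Of the single windows 38.4% lay in CHG-rich bins, and of those in long runs 91.8%. The CHH ratio was lower in long runs in either location. In CHG-rich bins it was 2.005 (1.95 to 2.08) in single windows and 1.79 (1.77 to 1.82) in runs of 10 or more. In other bins it was 2.15 (2.08 to 2.22) and 1.57 (1.51 to 1.62).

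On chromosome 2, between 3200000 and 3449999, 21 bins of 10 kb stood out by depth and low methylation. Their depth was 2.63 times the genome median in the seed coat and 4.92 times in the embryo library, and CHH was 0.260% and 0.320% with absent cytosines filled in. No explanation was tested.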
